A study of Homo sapiens with 20 samples.

How the data were processed

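The series measured where the histone variant H2A.Z and its acetylated form lie on the genome by chromatin immunoprecipitation followed by sequencing (ChIP-seq). All 20 libraries came from BT474, an established human breast cancer line with an amplified ERBB2 (HER2) gene and an active oestrogen receptor. The cells were parental or lacked BRD8, a bromodomain subunit of the NuA4/TIP60 histone acetyltransferase complex, and were given the solvent DMSO or neratinib, an irreversible inhibitor of the HER2 and EGFR kinases. Groups were taken from the labels. There were 8 immunoprecipitation groups of 2 libraries each (2 antibodies, 2 genotypes and 2 treatments) and 4 input libraries, 1 for each genotype and treatment. Per the labels' protocols, formaldehyde-fixed chromatin was sonicated and the libraries were sequenced as paired-end reads. Neither the dose nor the duration of neratinib was given in the sources used here.

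For each immunoprecipitation group the authors deposited 1 peak list, giving a chromosome, a start, an end, a name and 1 score per peak. The genome build was hg38, per the submitters' processing notes. The peak caller, the aligner, the threshold, the way the 2 libraries of a group were combined and the use of the input libraries were not given in the sources used here. The score in the deposited lists is the authors' own strength value of a peak. Its scale was not stated and its range differed between lists, from a median of 29.7 in the shortest list to 114 in the longest H2A.Z list, so it was used only to rank or filter peaks within a list. In every list the peaks were ordered by this score, and no rank number was missing. Starts were read as 0-based, as in BED files, and coordinates are printed 1-based. Each list covered the 22 autosomes and X. The commonest peak width differed between lists, from 576 bp in the H2A.Z list of knockout cells given neratinib to 870 bp in the acetylated H2A.Z list of parental cells given DMSO, and peaks of 1 list often overlapped each other. No column of the files was left unused.

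Because each group had 1 list and no values per library, there was no spread between replicates, and no test and no p-value could be given for any difference between groups. Read depth is unknown. Shares of peaks are given with Wilson 95% intervals. These cover counting error only and are too narrow as far as neighbouring peaks depend on each other. A peak counted as shared when it overlapped a peak of the compared list by at least 1 bp (bedtools 2.31.1). Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

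Peaks were tied to genes with a RefSeq table of assembly GRCh38.p14, the same build as hg38, which held 19974 protein-coding genes on these chromosomes. The plan fixed before the data were examined used promoters, but the gene table gave no strand. A gene therefore counted as occupied when a peak lay within 1000 bp of either annotated end, and such peaks are called gene-end peaks. Promoters inside a gene are missed by this rule, which matters for ESR1 and CDKN1A. For the genes named in every comparison, peaks anywhere in the gene or within 1000 bp of it were counted as well. Peaks that were not at a gene end were classed as inside a protein-coding gene (gene body) or between genes.

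A total of 19 gene lists with 458 genes were fixed before the data were examined, and all 458 symbols matched the gene table. For each list and comparison, the number of occupied members without a gene-end peak in the compared group was placed among 10000 random lists of the same size. The random lists were matched on the decile of peak strength in the group with the peaks, and lists with fewer than 5 occupied members were not placed. The resulting percentile describes these lists and is not a p-value; values below 2.5 or above 97.5 are called outside the middle 95%. The overlap of genes lacking a peak in 2 comparisons was set beside 1000 draws matched on the strength decile in both reference lists.

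The genes named follow a rule fixed before the data were examined. BRD8, ERBB2, ESR1, PGR, CDKN1A, MDM2, CCND1, MYC, H2AZ1, EP400 and KAT5 are named in each comparison. In each gene list the text leads with, up to 4 members with a different state are named, strongest peak first; for some lists the count alone is given. In each comparison and antibody, up to 5 protein-coding genes are named that had the strongest gene-end peak in 1 list and neither an overlapping nor a gene-end peak in the other, and 5 the other way round; in some comparisons fewer are named. Genes outside this rule are said to be chosen after their values were seen.

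The steps were tested on simulated data. Lists made from the merged parental DMSO regions with 39.9% to 80.0% of the regions kept gave back these shares exactly for both antibodies. This was fixed by construction, so it checks the counting step alone. It does not show how accurate the shares between the deposited lists are, whose peaks overlap each other and differ in width. For H2A.Z in parental cells with and without neratinib, 4.4% of 500 random lists of 20 genes drawn from 13572 occupied genes fell outside the middle 95%, and 84.4% of lists with 10 planted losses lay above it. With losses drawn from peak strength alone over 12754 genes, the observed number was 0.924 to 1.07 times the strength-matched one in 10 simulations, and with planted shared losses 1.39 to 1.49 times.

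Alternatives planned before the data were examined changed the overlap rule, the strength threshold, the length of the compared lists, the unit (base pairs in place of peaks), the width of the gene-end window and the genes of the 17q12 list. A common peak width of 500 bp, the removal of chromosomes 17 and 20, and peaks anywhere in a named gene were added after the data had been seen.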

Results

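H2A.Z replaces the ordinary histone H2A in nucleosomes near promoters and enhancers, and its acetylated form accompanies active chromatin. The series asked how loss of BRD8 and treatment with neratinib alter the places where both forms are found in BT474 cells. The data were 8 peak lists, 1 for each antibody, genotype and treatment, each standing for 2 libraries. With 1 list per group, every difference given here compares 2 lists and has no replicate check.

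Without neratinib the H2A.Z lists of parental and knockout cells were of similar length, and both H2A.Z lists from cells given neratinib were shorter. Parental cells had 62719 H2A.Z peaks in DMSO and 38935 with neratinib. Knockout cells had 61290 in DMSO and 28757 with neratinib. These peaks covered 39.2, 20.5, 36.5 and 13.8 Mb, in the same order. The lists of acetylated H2A.Z differed much less. They held 62008 peaks in parental cells given DMSO, 57609 in parental cells given neratinib, 63424 in knockout cells given DMSO and 58647 in knockout cells given neratinib.

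The shorter H2A.Z lists lay closer to genes. Gene-end peaks made up 38.8% (95% interval 38.4 to 39.1) of the H2A.Z list of parental cells in DMSO and 57.8% (57.3 to 58.2) with neratinib. In knockout cells the shares were 39.8% (39.4 to 40.2) and 59.6% (59.1 to 60.2). Peaks between genes made up 35.8% and 21.6% of the parental lists and 35.3% and 20.9% of the knockout lists, without and with neratinib. For acetylated H2A.Z the gene-end share was 32.2% and 32.1% in parental cells and 29.4% and 32.1% in knockout cells. In the strongest decile of each list, gene-end peaks made up 61.4% to 73.9%. Of the 19974 protein-coding genes, 14207 (71.1%) had a gene-end peak in at least 1 list.

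**Figure D1:**
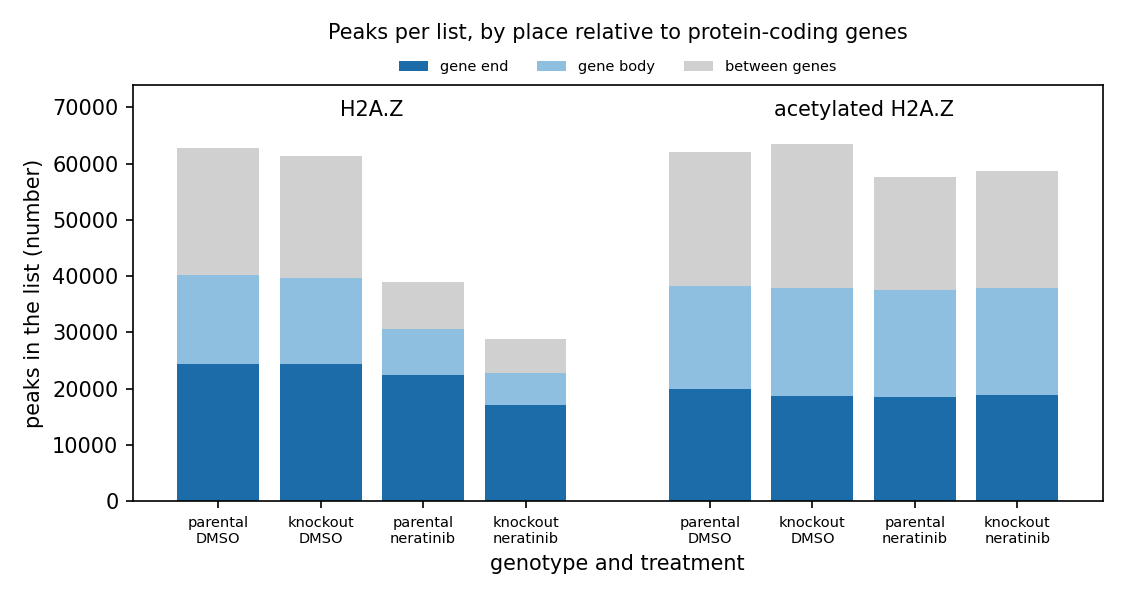
Number of peaks (vertical axis) in each of the 8 lists (horizontal axis: genotype and treatment, H2A.Z on the left and acetylated H2A.Z on the right), divided into peaks within 1000 bp of a gene end, inside a gene and between genes. The H2A.Z lists with neratinib hold 38935 and 28757 peaks against 62719 and 61290 without it, and the 4 lists of acetylated H2A.Z hold 57609 to 63424.

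BRD8, the targeted gene (chromosome 5, 138139770 to 138178630), had a gene-end peak in all 8 lists, the knockout lists included. A peak of H2A.Z at the gene does not show whether the protein is made, so these lists do not check the genotype labels. MDM2 (p53 antagonist), CCND1 (cyclin D1), MYC, H2AZ1 (a gene for H2A.Z itself), and EP400 and KAT5, 2 subunits of NuA4/TIP60, also had gene-end peaks in all 8 lists. KAT5 was among the strongest 1% of peaks in each list, from 0.126% to 0.965% from the top. PGR, the progesterone receptor gene and a classical oestrogen target, had one in 7 lists and lacked it only for acetylated H2A.Z in knockout cells given DMSO, where peaks inside the gene remained. ESR1, the oestrogen receptor gene, had gene-end peaks of acetylated H2A.Z in all 4 conditions and none of H2A.Z. Inside ESR1 the number of H2A.Z peaks was 14 in parental cells and 6 in knockout cells given DMSO, and 2 and 0 with neratinib. The number of acetylated H2A.Z peaks there was 30 and 21 in DMSO and 28 and 20 with neratinib. CDKN1A, the p21 gene, had no gene-end peak but had peaks inside the gene in all 8 lists. ERBB2 had no peak at its ends or inside it in any list.

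Loss of BRD8 was compared with parental cells in DMSO first. Most peaks were shared. A share of 79.0% (78.7 to 79.3) of the parental H2A.Z peaks and 80.5% (80.2 to 80.8) of the parental acetylated H2A.Z peaks overlapped a peak of the knockout list. At gene ends these shares were 90.9% and 88.2%, and between genes 70.8% and 77.1%. More genes had a gene-end peak in parental cells alone than in knockout cells alone, 818 against 276 for H2A.Z and 818 against 318 for acetylated H2A.Z. Of the genes named in each comparison, only PGR differed, by the acetylated H2A.Z peak described above. Among 26 oestrogen response genes with a parental acetylated H2A.Z peak, 3 lacked it in knockout cells (PGR, ELOVL2 and FOXC1), where matched random lists lacked 3.82 on average. TFF3 and SLC7A5 were the 2 of 26 that lacked H2A.Z.

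Luminal markers kept acetylated H2A.Z in the knockout. None of the 19 occupied luminal genes lacked the peak in knockout cells, against 4.31 expected for lists of the same peak strength (percentile 0.26; 2.68 with a window of 3000 bp and 3.78 with the stronger peaks alone). Genes for the machinery that handles H2A.Z were also mostly unaltered. All 19 NuA4/TIP60 subunit genes kept both marks, while YY1 and SRCAP, 2 of 18 genes of the SRCAP and INO80 remodellers, lacked H2A.Z in the knockout (0.36 expected). Of 17 acute stress genes, SESN2, DDIT3 and TRIB3 had H2A.Z in parental cells alone, and HSPA5, an endoplasmic reticulum chaperone gene, had it in knockout cells alone. Of 26 p53 target genes SESN2 lacked H2A.Z in the knockout and BBC3 had it there alone. All 26 DNA repair genes kept H2A.Z. Of 4 immune cell markers with acetylated H2A.Z in parental cells, CD68 lacked it in the knockout. The developmental genes LHX2 and PAX2 had H2A.Z in knockout cells alone.

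The strongest gene-end peaks found in 1 list alone came from few chromosomes. With H2A.Z, those of parental cells alone were at THRA (thyroid hormone receptor alpha; chromosome 17, 40062780 to 40064156, the strongest peak of the whole list), PNMT, TCAP, BCAS3 and CALCOCO2, all on chromosome 17. Those of knockout cells alone were at UCP2 on chromosome 11 and at COQ4, TRUB2, RABGAP1 and ZBTB26 on chromosome 9. PNMT and TCAP were counted on the same peak, as were COQ4 and TRUB2, and RABGAP1 and ZBTB26. With acetylated H2A.Z, those of parental cells alone were at THRA, BCAS3, MAP1LC3A, PNMT and TCAP, and those of knockout cells alone at COQ4, TRUB2, GAPVD1, ARRB1 and POLA2. Of 950 genes in the top 20% of peak strength for both antibodies in parental cells, 23 lacked H2A.Z and 15 lacked acetylated H2A.Z in the knockout, and 12 lacked both, where the product of the separate shares gives 0.363.

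Under neratinib a smaller share of the parental peaks overlapped a knockout peak than in DMSO. Of the parental H2A.Z peaks, 69.2% (68.7 to 69.7) overlapped a knockout peak, and of the parental acetylated H2A.Z peaks, 72.7% (72.3 to 73.1). In the other direction, 83.7% of the knockout H2A.Z peaks overlapped a parental peak, both in DMSO and with neratinib. For acetylated H2A.Z these shares were 79.9% in DMSO and 72.9% with neratinib. The 2 marks differed in direction at genes, but the H2A.Z lists also differed in length, with 38935 parental and 28757 knockout peaks. The acetylated H2A.Z lists were of similar length, with 57609 and 58647. Genes were not counted at equal list lengths, so the part of list length in the direction is unknown. For H2A.Z, 1788 genes had a gene-end peak in parental cells alone and 405 in knockout cells alone. For acetylated H2A.Z, 518 had one in parental cells alone and 1247 in knockout cells alone. None of the genes named in each comparison differed in whether either end had a peak, but the strongest H2A.Z gene-end peak of CCND1 was at its lower-coordinate end in parental and at its other end in knockout cells. Counted in base pairs, the shared part of the parental H2A.Z list was 46.0%.

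For H2A.Z, the luminal keratin genes KRT18 and KRT8 and the luminal gene AGR3 had a peak in knockout cells alone. These were 3 of 13 luminal markers against 0.54 expected (percentile 99.4), but whether KRT18 and KRT8 stand on the same peak was not checked. KRT7 and CLDN4 had an H2A.Z peak in parental cells alone (2 of 12, percentile 34.5). The developmental genes LHX2, PAX2 and OLIG2 had H2A.Z in knockout cells alone, 3 of 18 (percentile 98.7; 94.3 with the 3000 bp window and 59.4 with the stronger peaks alone), and WT1, HOXD8 and HOXA9 had it in parental cells alone, 3 of 18 (percentile 55.6). Of the immediate-early genes, the first to respond to growth factor signalling through MAP kinase, FOS, IER3, EGR1 and FOSB had acetylated H2A.Z in knockout cells and not in parental cells given neratinib, 4 of 17, which is inside the middle 95% (percentile 89.3). None of 22 oestrogen response genes lacked H2A.Z in the knockout (percentile 1.86; 15.3 with the wider window and 73.2 with the stronger peaks alone). For the FOXO and feedback targets, 5 of 17 lacked H2A.Z in knockout cells, led by ERBB3, TXNIP, INSR and CITED2 (percentile 93.9), and all of them kept acetylated H2A.Z. The p53 targets TRIAP1, GADD45A and BBC3 lacked acetylated H2A.Z in the knockout (3 of 22 against 0.83 expected; percentile 49.3 with the wider window and 89.1 with the stronger peaks alone), while SESN2, PLK3, PLK2 and SPATA18 had it there alone. Of 18 NuA4/TIP60 subunit genes, MORF4L1, MEAF6 and RUVBL2 lacked H2A.Z in the knockout.

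The strongest H2A.Z peaks of parental cells alone under neratinib were at VAPB, MAP1LC3A, CYFIP1, ZC3H14 and TARS2, and those of knockout cells alone at THRA, DHX40, RAB22A, PNMT and BCAS3. With acetylated H2A.Z they were at VAPB, MAP1LC3A, TARS2, CALCOCO2 and MRPL45 for parental cells and at BCAS3, BCAS1, DHX40, RAB22A and PNMT for knockout cells. THRA, PNMT and BCAS3 had been parental-only in DMSO, so their direction was the opposite with neratinib.

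Neratinib was then compared with DMSO within each genotype. In parental cells 92.4% of the H2A.Z peaks and 74.7% of the acetylated H2A.Z peaks of the neratinib list overlapped a peak of the DMSO list. Of the DMSO list, 54.3% (53.9 to 54.7) of the H2A.Z peaks and 65.2% (64.8 to 65.6) of the acetylated H2A.Z peaks overlapped a neratinib peak. The H2A.Z peaks that were shared lay mostly at genes. At gene ends 80.8% (80.3 to 81.3) of them were shared, inside genes 42.8% (42.0 to 43.6) and between genes 33.8% (33.2 to 34.4). For acetylated H2A.Z these shares were 74.7%, 63.1% and 58.8%. A gene-end peak without neratinib alone was found at 1820 genes for H2A.Z and 1943 for acetylated H2A.Z, and one with neratinib alone at 104 and 209. None of the genes named in each comparison differed in whether either end had a peak, but the strongest acetylated H2A.Z gene-end peak of ESR1 was at its lower-coordinate end in DMSO and at its other end with neratinib.

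Several immediate-early genes had acetylated H2A.Z in parental cells given DMSO and not with neratinib. Of 20 that were occupied in DMSO, 8 had no peak with neratinib, against 4.34 expected (percentile 98.5; 69.6 with a window of 3000 bp and 90.9 with the stronger peaks alone). The 4 with the strongest peaks were FOS, IER3, EGR1 and FOSB. DUSP4, a MAP kinase phosphatase gene, had a peak of both marks with neratinib alone. Luminal markers kept acetylated H2A.Z, with 2 of 19 (GATA3 and KRT18) lacking it against 8.25 expected (percentile 0.010; 34.2 with the stronger peaks alone). All 20 FOXO and feedback targets kept it (percentile 2.28; 3.67 with the wider window). Of 14 basal and mesenchymal markers, 7 lacked it, led by COL1A1, SNAI1, FN1 and SNAI2 (percentile 95.3). For H2A.Z, the stress genes HSPA5 and XBP1 had a peak with neratinib alone (2 of 18 against 0.23 expected; percentile 99.0, and 91.8 with the wider window). HSPA5 is among the genes that had strong peaks of both marks in some conditions and none in others. The oestrogen response genes FOXC1, ELOVL2, TFF1 and TFF3 were among 5 of 26 without H2A.Z under neratinib (percentile 87.7). Among 32 cell cycle genes regulated by E2F, CCNB1, MKI67 and E2F1 lacked it (percentile 34.6). All 24 cholesterol synthesis genes with acetylated H2A.Z kept it, against 2.20 expected to lack it (percentile 2.56). For the interferon response 4 of 23 lacked H2A.Z (percentile 35.5), and for ribosomal proteins 3 of 29 (percentile 11.5). For the BCL2 family and other apoptosis genes it was 3 of 21 (percentile 87.1), for the ERBB and receptor tyrosine kinase genes 3 of 30 (percentile 9.80), and for the developmental genes 3 of 21 (percentile 53.1).

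The strongest H2A.Z peaks of parental cells without neratinib alone were at THRA, PNMT, TCAP, BCAS3 and SNF8, and those with neratinib alone at VAPB, ZNF669, RAC1, GAPVD1 and STIP1. For acetylated H2A.Z they were at SNF8, BCAS1, BCAS3, PNMT and TCAP without neratinib, and at VAPB, GAPVD1, PPP6C, HSPA5 and OTUB1 with it.

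In knockout cells neratinib was accompanied by a larger difference in H2A.Z and a smaller one in acetylated H2A.Z than in parental cells; the difference between the genotypes was not tested. Of the knockout neratinib peaks, 88.8% of H2A.Z and 81.4% of acetylated H2A.Z overlapped a DMSO peak. Of the knockout DMSO peaks, 46.7% (46.3 to 47.1) of H2A.Z and 72.6% (72.2 to 72.9) of acetylated H2A.Z overlapped a neratinib peak. When the strongest peaks of both lists were taken at equal lengths, the H2A.Z share was 71.5% in knockout and 73.1% in parental cells, nearly the same. In base pairs it was 27.0% and 36.9%. At gene ends 73.4% of the H2A.Z peaks were shared, between genes 25.8%. A gene-end peak without neratinib alone was found at 2793 genes for H2A.Z and 914 for acetylated H2A.Z, and one with neratinib alone at 236 and 409. PGR had its acetylated H2A.Z gene-end peak with neratinib alone, and the others of the genes named in each comparison did not differ in whether either end had a peak, though the strongest such peak changed ends at CCND1 (H2A.Z) and ESR1 (acetylated H2A.Z).

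Of the acute stress genes, XBP1, DDIT3, TRIB3 and SESN2 had H2A.Z with neratinib alone. These were 4 of 17 against 0.43 expected (percentile 99.9, and 97.0 with the 3000 bp window). However, DDIT3, TRIB3 and SESN2 also had H2A.Z in parental cells with both treatments. They lacked it only in knockout cells given DMSO, so their difference rests on that list. NUPR1 and PHGDH had H2A.Z in DMSO alone (2 of 15, percentile 21.2). The luminal genes XBP1, KRT18 and KRT8 had H2A.Z with neratinib alone (3 of 13, percentile 99.9, and 88.9 with the wider window). KRT18 and KRT8 had the same H2A.Z state in every condition, and whether they stand on the same peak was not checked. The number of luminal genes with H2A.Z was 13 in both lists. Immediate-early genes kept H2A.Z, with 1 of 20 (ETV4) lacking it against 4.96 expected (percentile 0.75), and DUSP4 again had both marks with neratinib alone. The ERBB and receptor tyrosine kinase genes lacked H2A.Z less often than matched lists, 4 of 29 (ERBB3, FGFR1, INSR and NRG1) against 7.90 (percentile 2.45, and 2.54 without the 17q12 genes). Of 26 p53 targets 6 lacked it, led by SPATA18, BBC3, SUSD6 and PLK3 (percentile 87.1).

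The strongest H2A.Z peaks of knockout cells without neratinib alone were at SNF8, ATG4D, CYFIP1, ZC3H14 and COQ4, and those with neratinib alone at THRA, DHX40, RAB22A, PNMT and UQCC1. For acetylated H2A.Z they were at COQ4, TRUB2, SNF8, PPP6R3 and ARRB1 without neratinib, and at BCAS3, THRA, DHX40, RAB22A and PNMT with it.

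In all 4 comparisons the strong peaks were retained much more often than the weak ones. In the top decile of strength 92.3% to 99.2% of peaks were shared. In the bottom decile 25.6% and 26.4% of H2A.Z peaks were shared between DMSO and neratinib, and 45.3% to 60.3% in the other comparisons. The bottom decile was not the least shared one. In decile 2 the H2A.Z shares between DMSO and neratinib were 15.5% in parental and 15.3% in knockout cells. For each comparison and antibody the lowest share was in decile 2 or 3. Over the 4 comparisons, 2 antibodies and 19 gene lists, 282 percentiles were computed and 21 lay outside the middle 95%, where 14.1 are expected. A group of 8 of the 21 belonged to the list of 17q12 genes, and without the genes of that list 12 of 274 lay outside, where 13.7 are expected.

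**Figure D2:**
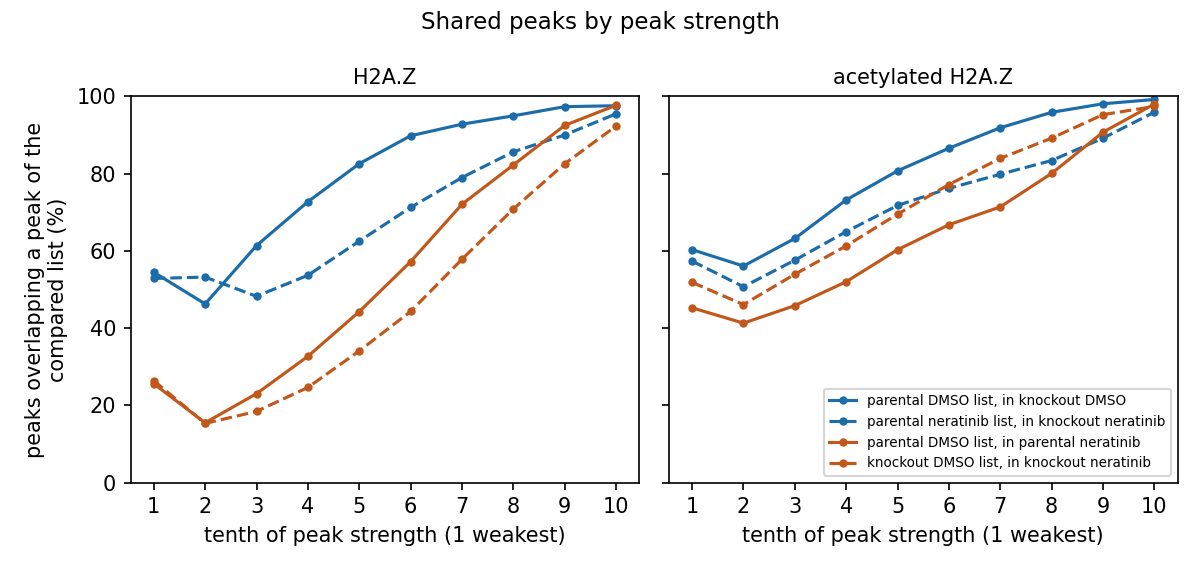
Percent of peaks of the first list that overlap a peak of the compared list (vertical axis) by decile of peak strength in the first list (horizontal axis, 1 weakest), for H2A.Z and acetylated H2A.Z, with 1 line for each comparison. The top decile lies between 92.3% and 99.2% in all lines, and the bottom decile of H2A.Z under neratinib is at 25.6% in parental and 26.4% in knockout cells. The lowest point of each line is at decile 2 or 3 and not at the weakest decile.

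Acetylated H2A.Z is a form of H2A.Z, so an acetylated peak without an H2A.Z peak means only that no H2A.Z peak was called there. Genes described as without H2A.Z lacked a called peak, which does not show that H2A.Z was absent. Acetylated H2A.Z was set beside total H2A.Z of the same cells to see how far its peaks lay on called H2A.Z peaks. In parental cells 71.0% (70.7 to 71.4) did so in DMSO and 45.7% (45.3 to 46.1) with neratinib. In knockout cells 63.6% (63.2 to 64.0) and 38.0% (37.6 to 38.3) did. With the strongest peaks taken at equal lengths, the shares with neratinib were 54.5% and 52.7%, and in base pairs they were 30.7% and 23.8%. In the other direction, 71.8% to 78.5% of the H2A.Z peaks lay on acetylated H2A.Z peaks. Acetylated H2A.Z peaks without an H2A.Z peak lay away from gene ends, with 7.83% to 14.5% at gene ends against 41.8% to 60.8% of those with one.

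Luminal markers had acetylated H2A.Z without an H2A.Z peak more often than matched lists. In parental cells given DMSO this held for 5 of 19 occupied genes against 1.31 expected (percentile 99.7), led by KRT19, XBP1, KRT18 and ESR1. In knockout cells given DMSO it held for 8 of 21 against 1.71 (percentile 100), led by KRT7, ESR1, XBP1 and KRT18, and in parental cells given neratinib for 7 of 18 (percentile 99.8). With the stronger peaks alone these percentiles were 94.1, 84.8 and 67.5, and with the 3000 bp window the first was 97.4. With neratinib in the knockout it was 6 of 19 (percentile 76.1). Some developmental genes bound by polycomb had H2A.Z without acetylated H2A.Z. In parental cells given DMSO this held for 6 of 21 against 2.04 expected (percentile 99.8), and with neratinib for 6 of 18 (percentile 97.9). In knockout cells given DMSO it held for 6 of 22 (percentile 97.6; 94.0 with the 3000 bp window and 95.3 with the stronger peaks alone), and with neratinib the percentile of 97.0 was inside the middle 95%. Basal and mesenchymal markers had H2A.Z alone in parental cells given neratinib, with 6 of 12 (led by COL1A1, SNAI1, CDH2 and CAV1) against 1.43 (percentile 99.9). Ribosomal protein genes with H2A.Z all had acetylated H2A.Z in DMSO, 29 of them in parental and 27 in knockout cells (percentiles 0.68 and 0.88). Of the FOXO and feedback targets, 8 of 20 had acetylated H2A.Z without a called H2A.Z peak in knockout cells given neratinib (percentile 99.8). They were led by INSR, ERBB3, CITED2 and TXNIP. The H2A.Z list of that condition was the shortest, with 28757 peaks against 58647 acetylated ones. Of 141 percentiles in these comparisons 20 lay outside the middle 95%, where 7.05 are expected, and 20 of 137 did so without the 17q12 genes.

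Of the genes named in each comparison, ESR1 had acetylated H2A.Z without H2A.Z at its ends in all 4 conditions, and PGR had H2A.Z without acetylated H2A.Z in knockout cells given DMSO. Among the strongest gene-end peaks of acetylated H2A.Z without H2A.Z were those at RPLP0, HAX1, UBAP2L and ECH1 in parental cells given DMSO, and those at PMF1, PMF1-BGLAP, UBE2Z, PPP6R3 and POLDIP3 in knockout cells given DMSO. With neratinib they included those at ALDH3B2, NCOA4, SP100, ATP5F1B and UBXN2B in parental cells and at PSMD1, SUGT1, PPP1R10 and STAM in knockout cells. HAX1 and UBAP2L were counted on the same peak, as were PMF1 and PMF1-BGLAP. The strongest of H2A.Z without acetylated H2A.Z were at TTLL6, EGFLAM, TRPC6, GYG2 and CFAP300 in parental cells given DMSO, and at TTLL6, SAMD14, PRAC2, C7orf57 and SUN3 in knockout cells given DMSO, where C7orf57 and SUN3 share a peak. With neratinib they were at NRXN2, PHOSPHO1, SAMD14, PPM1E and PPDPF in parental cells and at UQCC1, CALCOCO2, MRPL45, PHOSPHO1 and ADA in knockout cells.

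The region around ERBB2 on chromosome 17 differed from all of this. A list of 20 genes from the 17q12 amplicon, the DNA segment that is multiplied in HER2-positive cancer, had gene-end peaks by condition and not by antibody. In parental cells given DMSO 6 of the 20 had H2A.Z and 6 had acetylated H2A.Z. In knockout cells given DMSO 1 had H2A.Z and 1 acetylated H2A.Z, in parental cells given neratinib 0 and 1, and in knockout cells given neratinib 7 and 7. NEUROD2, STARD3, TCAP, PNMT and THRA had both marks in parental cells given DMSO and in knockout cells given neratinib, and neither mark in the other conditions. PNMT and TCAP share a peak, so the 7 genes of the list with a peak in any of the 8 lists stand for 6 separate ones. The list stood at percentile 100 in each of the 8 comparisons that gave it a value outside the middle 95%. These values are not separate results, since all start from the lists of parental cells given DMSO or of knockout cells given neratinib. The random lists drew genes singly from all chromosomes, while the 17q12 genes are neighbours. A single difference of the region can thus count as several genes, and the percentile overstates how unusual the list is. In this region around ERBB2 on chromosome 17, 3 intervals of over 200000 bp held no peak in any of the 8 lists. They ran from 38734734 to 39035602, from 39036681 to 39600779 and from 39671429 to 40062093. They hold 28 protein-coding genes from end to end, among them ERBB2, GRB7, MED1, CDK12 and the genes for the ribosomal proteins RPL19 and RPL23, which are named here after the intervals had been seen.

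**Figure D3:**
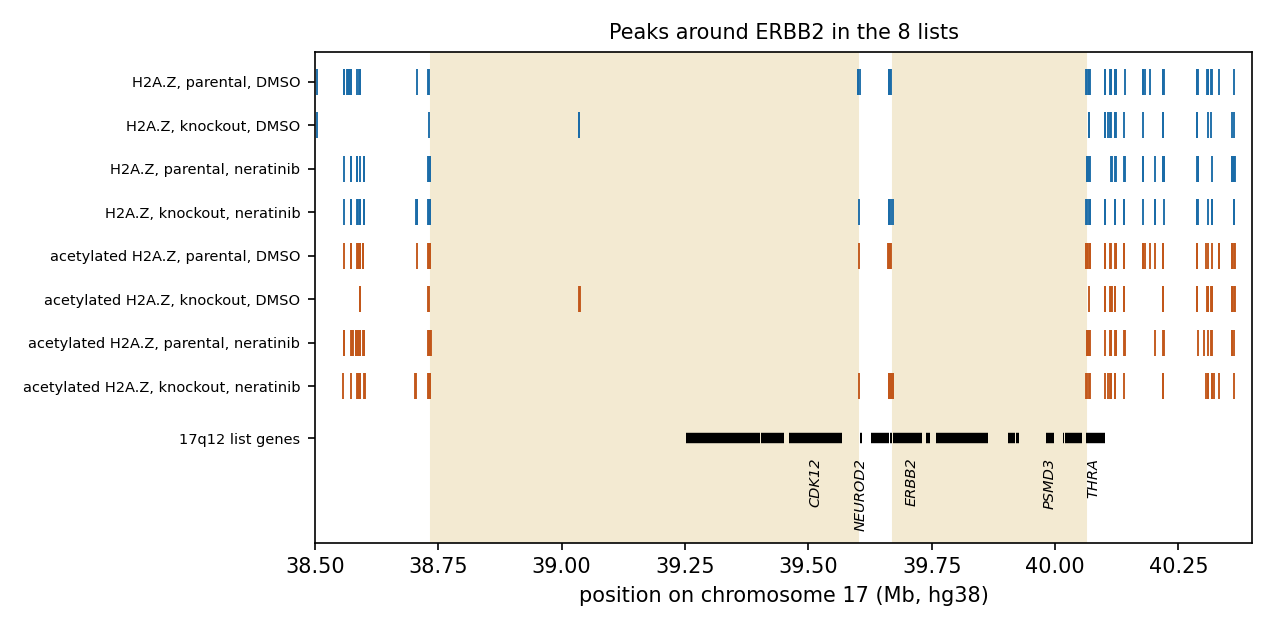
Map of chromosome 17 around ERBB2 (horizontal axis, position in Mb on hg38), with 1 line for each of the 8 lists (blue, H2A.Z; orange, acetylated H2A.Z), a vertical tick at the midpoint of each peak, the 17q12 list genes as black bars and the 3 peak-free intervals shaded. Peaks between 39600780 and 39671428 occur in parental cells given DMSO and in knockout cells given neratinib, with both antibodies.

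Elsewhere, too, genes had strong peaks of both marks in some conditions and no peak of either mark in others. Over the 8 ordered comparisons, 64 of 6392 pairs of a strong gene and a comparison lacked both marks in the compared condition, where separate shares give 1.37. These pairs came from 34 genes (32 separate peaks), a set chosen after its values were seen. Of the 34, 11 lie on chromosome 9, 8 on chromosome 11, 7 on chromosome 17 and 5 on chromosome 20. Together these chromosomes hold 31 of the 34 genes, against 18.95% of all tested genes. This contrast is a description only, since the chromosomes were picked because these genes lie on them. The base was not limited to genes with strong peaks, and some of the 34 are neighbours, such as PPP6C, HSPA5 and GAPVD1. SNF8 had both marks only without neratinib and ZNF669 only with it. DOLPP1, MAP1LC3A and TARS2 had them in parental cells alone, UCP2 in knockout cells alone. The other 28 genes had another pattern, and 15 of the 34 lacked both marks in a single condition. Both marks were present in knockout cells with neratinib alone at DHX40 and RAB22A, in parental cells with neratinib alone at VAPB, and in knockout cells in DMSO alone at COQ4, TRUB2 and POLA2. THRA, PNMT, TCAP and BCAS3 had both marks in parental cells given DMSO and in knockout cells given neratinib.

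**Figure D4:**
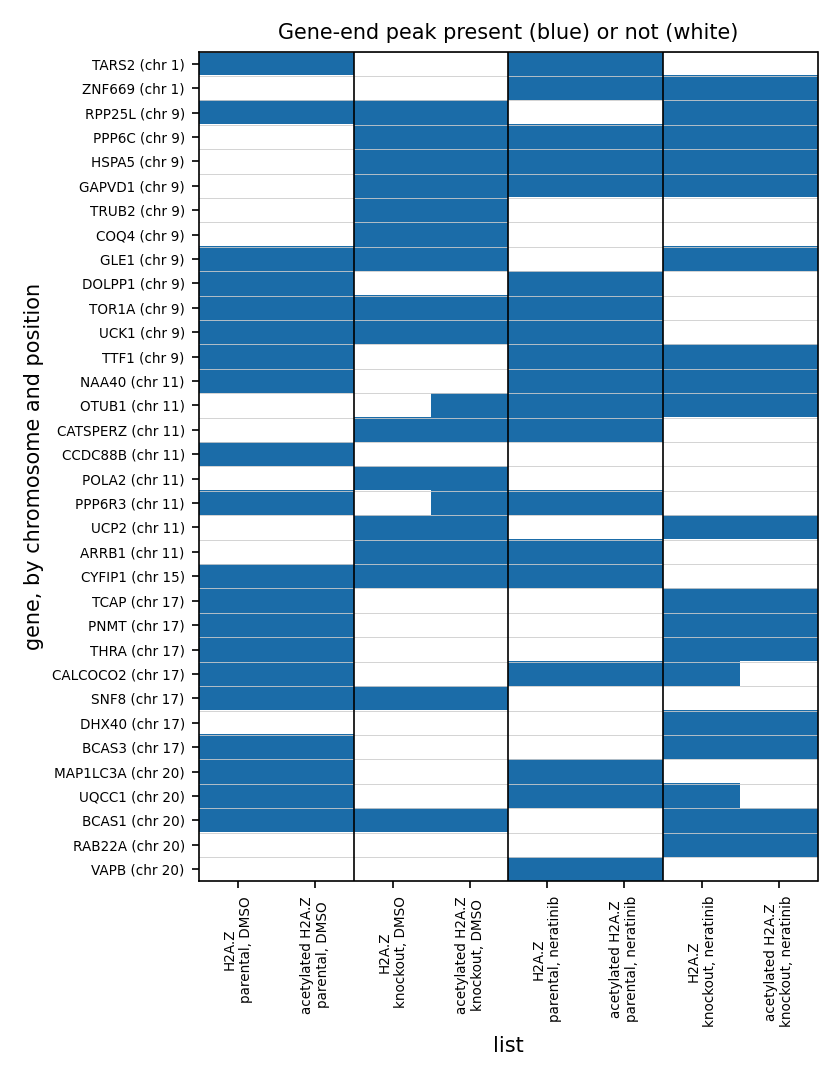
Gene-end peaks at the 34 genes (one line per gene, by chromosome) in the 8 lists (columns, both antibodies of a condition side by side), with blue for a peak and white for none. Conditions not used to choose a gene gave 39 cases, and the antibodies had the same state in 35 of them, 89.7% (76.4 to 95.9). The share for all genes with a peak was 84.4%, which was not limited to genes whose state varies and is no baseline for these genes.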

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

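Of the tests in this part, those of separate misses, of a single factor and of a shared processing step were chosen only after the result was seen. The list of 17q12 genes drew attention because its gene-end peaks changed in opposite directions with neratinib in the 2 genotypes. For H2A.Z the number of occupied genes was lower by 6 with neratinib in parental cells and higher by 6 in knockout cells, a gap of 12 genes. For acetylated H2A.Z it was lower by 5 and higher by 6, a gap of 11. The difference was not tested, since each genotype and treatment has 1 list.

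Together with this list, the 34 genes with strong peaks of both marks in some conditions and no peak of either mark in others were weighed as 1 pattern. Separate misses near the threshold in each list would give 1.37 such pairs, and the observed number was 46.7 times that; graded weakening would leave many strong genes weak in the compared condition, but 0 of them were below the list median with both antibodies. An effect of genotype or neratinib that is the same in both arms of the other factor would give the pattern of 6 genes and not that of the other 28. Both sets of genes were grouped by their pattern, and each antibody has 1 list per condition. The numbers 6 and 28 therefore cannot decide on such an effect, which stays open. NEUROD2, STARD3, TCAP, PNMT and THRA changed in opposite directions with neratinib in the 2 genotypes, with both antibodies. Such an effect alone would not give the states of these genes, but each state rests on 1 list. TCAP, PNMT and THRA are also among the 28, so they are not separate evidence. A step of the authors' processing that both antibodies of a condition share, such as a filter made from its single input library, cannot be told apart from other sources. The antibodies had the same state in 89.7% of the 39 cases not used to choose the genes, with an interval of 76.4% to 95.9%. The 84.4% of all genes with a peak was not limited to genes whose state varies. It is therefore no baseline for these genes, and the agreement does not decide between the sources. A difference in DNA content or chromatin of these loci stays open as untested.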

How the results depend on the processing

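The width of 500 bp, the removal of chromosomes 17 and 20, and peaks anywhere in a named gene were chosen after seeing the data. No paired analysis was possible because each group is 1 list that stands for both of its libraries. For the same reason, leaving out a replicate was not possible, and rules that need values per library were not run. A common median strength was not run because the scores have no common unit, and classes of peaks by the authors were not run because the lists give none. What depth limits is unknown, since depth was not given in the sources used here.

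Shares are given in the order knockout against parental cells in DMSO, the same in neratinib, neratinib in parental cells and neratinib in knockout cells. Acetylated peaks on H2A.Z peaks are given for parental and knockout cells in DMSO, then for both with neratinib. When shared peaks had to overlap by 50% of the smaller peak, the shares were 75.3, 61.7, 49.4 and 41.3% for H2A.Z, 75.7, 62.2, 58.1 and 66.8% for acetylated H2A.Z, and 65.8, 58.3, 36.7 and 32.4% for acetylated peaks on H2A.Z peaks. With peaks within 1000 bp merged first, they were 76.0, 68.1, 49.4 and 40.6% for H2A.Z, 80.8, 77.9, 66.4 and 72.9% for acetylated H2A.Z, and 72.9, 67.1, 49.3 and 39.9% for acetylated peaks on H2A.Z peaks. With peaks above the median strength of both lists, they were 84.4, 67.0, 59.8 and 49.1% for H2A.Z, 82.3, 70.7, 63.4 and 73.4% for acetylated H2A.Z, and 69.4, 60.8, 42.1 and 36.4% for acetylated peaks on H2A.Z peaks. With the first list alone limited to peaks above its median, they were 94.5, 84.3, 80.4 and 69.6% for H2A.Z, 94.3, 84.9, 81.4 and 88.6% for acetylated H2A.Z, and 86.7, 78.4, 60.8 and 52.4% for acetylated peaks on H2A.Z peaks.

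With the strongest peaks of both lists at equal lengths, they were 79.4, 75.4, 73.1 and 71.5% for H2A.Z, 80.4, 72.5, 66.7 and 74.3% for acetylated H2A.Z, and 71.0, 64.2, 54.5 and 52.7% for acetylated peaks on H2A.Z peaks. In base pairs in place of peaks, they were 62.0, 46.0, 36.9 and 27.0% for H2A.Z, 62.8, 53.2, 44.4 and 54.0% for acetylated H2A.Z, and 53.9, 48.1, 30.7 and 23.8% for acetylated peaks on H2A.Z peaks. With every peak set to 500 bp around its midpoint, they were 77.1, 67.3, 52.2 and 45.0% for H2A.Z, 77.9, 69.6, 62.4 and 69.8% for acetylated H2A.Z, and 68.1, 61.0, 43.0 and 36.5% for acetylated peaks on H2A.Z peaks. Without chromosomes 17 and 20, they were 79.6, 69.8, 55.1 and 46.9% for H2A.Z, 81.3, 73.4, 65.3 and 72.3% for acetylated H2A.Z, and 70.0, 62.5, 45.2 and 37.3% for acetylated peaks on H2A.Z peaks. A longer required overlap leaves fewer matches by construction, and counting base pairs gives no credit for the rest of a matched peak. For the other settings the cause was not tested.

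The gene-end share of the lists is given for parental and knockout cells in DMSO, then for both with neratinib. With a window of 3000 bp it was 45.1, 45.7, 64.0 and 66.2% for H2A.Z and 38.1, 34.7, 39.0 and 37.8% for acetylated H2A.Z, since a wider window takes in more peaks by construction. Without chromosomes 17 and 20 it was 40.8, 42.0, 60.4 and 63.1% and 32.5, 29.5, 32.7 and 32.9%, and the cause was not tested. In both, the H2A.Z share was higher with neratinib than in DMSO in each genotype.

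Of the 21 list percentiles outside the middle 95% in the knockout and neratinib comparisons, 12 stayed outside with the 3000 bp window, 12 with the stronger peaks alone, and 13 without chromosomes 17 and 20. Of the 13 that did not belong to the 17q12 list, 4, 6 and 13 stayed outside, in the same order. Without the genes of the 17q12 list 12 of 274 percentiles lay outside, where 13.7 are expected, since 8 of the 21 came from that list and the list of ERBB and receptor tyrosine kinase genes moved from 2.45 to 2.54. Of the 20 in the comparison of acetylated with total H2A.Z, 14, 10 and 17 stayed outside, and all 20 did without the 17q12 genes. With peaks anywhere in the gene, ESR1 had a peak in 7 lists in place of 4, PGR in 8 in place of 7 and CDKN1A in 8 in place of 0, while ERBB2 stayed at 0.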

Other observations

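Of the tests in this part, those of peak strength alone and of a common width of 500 bp were chosen after the result was seen.

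The shorter H2A.Z lists with a higher gene-end share under neratinib were weighed first. Lower sensitivity that drops the weakest peaks first may account for it in knockout cells, where the strongest DMSO peaks at the length of the neratinib list had a gene-end share of 58.1%, against 59.6% in the neratinib list. In parental cells this gave 52.4% against 57.8%, which leaves 5.38 percentage points that lower sensitivity of this kind does not give. Within deciles of strength, gene-end peaks were shared more often than peaks between genes by 24.6 points on average in parental cells (0.25 to 41.9 between deciles), so loss away from gene ends at equal strength may contribute to the pattern, but the difference was larger in knockout cells (30.9 points), where only 1.52 points remained, so it does not track the remainder. With all peaks set to 500 bp the shared part in parental cells was 52.2%, but this is below the commonest widths of both lists, 844 and 720 bp, and trimming mostly removes overlaps, so a part of the different widths cannot be told apart from the rest, and whether the loss comes from neratinib or from the quality of the immunoprecipitation stays open.

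Genes that lacked H2A.Z under neratinib in both genotypes were weighed as another pattern. There were 961 of them among 12754 genes, and the highest of 1000 draws matched on peak strength was 789. Strength at the level of score deciles does not give this number. Differences in strength within a decile were not matched, so strength is not excluded. Neighbouring genes can be counted on the same peak but were drawn separately, which can make the draws too narrow. Genes whose peaks are called unevenly whatever the condition would also raise the number of genes with opposite directions in the 2 genotypes, which was 28 against 15.1 in matched draws, a ratio of 1.86. The ratio for the same direction was 1.30 and could at most have been 1.75, so the 2 ratios cannot be compared and this source cannot be told apart from a shared loss. Simulated shared losses gave ratios of 1.39 to 1.49, but their planted size was arbitrary and their loss rates were not set to those of the data. They are therefore no scale for the observed ratio.

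In the same way 23 genes had H2A.Z only with neratinib in both genotypes against 1.69 in matched draws, and 138 lacked it in the knockout under both treatments against 91.7. For acetylated H2A.Z 425 genes lacked a peak with neratinib in both genotypes against 293, and 89 lacked it in the knockout under both treatments against 31.0. Opposite directions with neratinib in the 2 genotypes were also more common for acetylated H2A.Z than in matched draws, with 30 genes against 14.0 (ratio 2.14) and 138 against 108 (ratio 1.28), beside a ratio of 1.45 for the same direction, so unevenly called genes stay open here as well.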
